A study of Mus musculus with 72 samples.

How the data were processed

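Gene expression was measured on 72 Affymetrix Mouse Gene 1.0 ST arrays with total RNA from bone marrow of mice with acute promyelocytic leukaemia (APL). The labels give each array a model (transgenic or viral transduction), a fusion protein, a background (Pml wild type or Pml null), a treatment (none or retinoic acid, RA), a time and a batch. This made 16 groups of 2 to 8 arrays in 4 batches, and each model of 36 arrays had batches of its own. The labels do not say whether arrays of a group came from separate animals or separate leukaemias, so every p-value measures the spread between these arrays.

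The deposited values are on the log2 scale, with 35556 values per array and no missing value. Per the submitters' processing notes, RMA and the affy package were used; their versions, the background correction, the probe set definition and any batch correction are not given in the sources used here. The authors' values ran from 2.60 to 14.24, and the array medians from 6.56 to 6.81. No pair of arrays was identical, the highest correlation between arrays was 0.998 and the lowest within a model 0.948. For arrays, the number of arrays per group limits the precision, and the median residual SD of a gene was 0.149 in the transgenic and 0.153 in the viral model, each with 27 residual degrees of freedom.

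Probe sets were assigned to genes with the annotation table of the platform, in which 23410 of the 35556 probe sets are listed, 21789 of them with exactly 1 gene symbol and 1621 with several. The other 12146 probe sets are not listed. A gene was represented by its probe set with the highest mean over the 72 arrays, which concerned 999 genes with several probe sets and gave 19938 genes. No genes were left out for low signal. Probe sets without a single symbol were tested apart and are given only as counts. Some members of the gene lists, and 2 of the 12 genes of a fixed panel, were not analysed here.

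The analysis was run in R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1. For each model, limma was fitted to all 36 arrays with 1 coefficient per group and an additive batch term, followed by eBayes with its default prior. All limma tests were two-sided. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 19938 genes were counted as called, and the calls with a change of at least 1.5-fold were counted beside them. There were 14 contrasts. They comprised the RA effect (RA minus untreated at the same time) in each of the 4 leukaemia types at 6 h and 12 h, the difference in RA effect within each model averaged over both times, the untreated difference within each model averaged over both times, and the change of the RA effect from 6 h to 12 h in the transgenic PML/RARA and the viral Pml wild type leukaemias. The transgenic and viral models share no batch, so their values were compared only through contrasts within a model.

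A set of 20 gene lists with 355 genes was written from textbook knowledge. It covered p53 targets, retinoic acid targets, secondary granule and mature neutrophil genes, primary granule and promyelocyte genes, stem and progenitor genes, senescence, the PML nuclear body, Myc and ribosome biogenesis, the cell cycle, the interferon response, apoptosis regulators, immediate early and stress genes, and coagulation and fibrinolysis. Further lists held markers of erythroid cells, B cells, T and NK cells, monocytes and macrophages, eosinophils with basophils and mast cells, megakaryocytes and platelets, and stroma and endothelium. A list was called when camera with a preset correlation between genes of 0.01 gave an adjusted p below 0.05 over the 20 lists of a contrast. The same test with a correlation estimated from the data was run beside it, as was fry. Members were counted with the p adjusted over all genes and with the p adjusted over the list alone. A list score, the mean log2 value of a list on each array, was compared between RA and untreated arrays by an exact two-sided permutation test that exchanged arrays only within their batch, with adjustment over the family of lists and groups.

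The named genes follow a rule. They are the 10 largest rises and the 10 largest falls among called genes in the 8 RA effects, the 2 differences in RA effect and the 2 untreated contrasts, without clone or predicted names, histone clusters and olfactory receptors. Up to 4 members of each list with the largest moderated statistic and the fixed panel were added. Any other gene is named only with a statement that it was chosen after its values were seen. The groups, contrasts, lists, naming rule, nearly all tests and nearly all alternatives were fixed before the data were examined.

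The fits were tested on simulated data built from the residuals of the arrays, with 20 runs and 50 changed genes per size of change. For the RA effect in transgenic PML/RARA leukaemia at 6 h, 36.5% of changes of 1.25-fold, 90.2% of 1.5-fold and 98.7% of 2-fold were recovered, with a mean of 3.8 false calls. For PLZF/RARA at 6 h these shares were 11.4%, 64.1% and 95.2%, with 4.4 false calls. For the difference between them they were 22.2%, 79.0% and 97.9%, with 3.15 false calls. An even shift of 0.3 of the p53 list, with no real RA effect, was called in 100% of runs with either form of camera. The 100% need not hold beside real RA effects. Unshifted lists were called in 20.8% to 26.6% of cases with the preset and in 0% with the estimated correlation. A call with the preset correlation alone is thus weak evidence.

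The alternatives changed the batch term, the arrays in the fit, the prior of the variance, a filter on the dimmest 33.3% of genes, the normalization (quantile normalization of each model again), array weights, the choice of probe set, the fold threshold, the control arrays and the time, ran within single batches, and left out each array in turn. Leaving out the arrays of unusual median, and single arrays for genes shared between effects, was chosen after seeing the data. Other splits of the same arrays, up to 100 per contrast, were fitted to ask how many genes a grouping by chance would call.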

Results

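The arrays measured gene expression in bone marrow from mouse models of APL, a leukaemia driven by fusions of the retinoic acid receptor alpha (RARA). In the transgenic model the fusion was PML/RARA, or PLZF/RARA, the fusion of a form of APL known to respond poorly to retinoic acid in patients. In the viral model, PML/RARA was carried by leukaemias labelled Pml wild type or Pml null. The transgenic PML/RARA groups held 4 untreated and 8 RA arrays at each of 6 h and 12 h, and the PLZF/RARA groups 2 untreated and 4 RA arrays at each time. Each viral background held 4 untreated and 8 RA arrays at 6 h, and 2 untreated and 4 RA arrays at 12 h. Unless said otherwise, changes are log2 fold changes with their standard error (SE).

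The first comparison asked what RA does to gene expression in leukaemias with PML/RARA. In transgenic PML/RARA leukaemia (8 RA and 4 untreated arrays at each time), single genes changed strongly within 6 h. Cyp26a1, the enzyme that breaks down retinoic acid, rose by 3.42 ± 0.54 at 6 h and by 3.90 ± 0.53 at 12 h. Fcgr4, a receptor for IgG on myeloid cells, rose by 3.15 ± 0.21 and 3.84 ± 0.20, and Ncf1, a subunit of the phagocyte NADPH oxidase, by 2.45 ± 0.18 and 2.66 ± 0.17. F3, tissue factor, which starts blood coagulation, rose by 2.94 ± 0.43 and 3.06 ± 0.42. Pml rose by 1.18 ± 0.11 and 1.17 ± 0.11, while Kit, a growth factor receptor of progenitor cells, fell at both times (-1.30 ± 0.16 and -1.29 ± 0.16).

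Other large rises at 6 h were those of Suox (sulfite oxidase, 3.08 ± 0.34), the transcriptional repressor Hic1 (2.61 ± 0.36) and Adssl1 (an enzyme of AMP synthesis, 2.60 ± 0.17). They also included Irak2 (a kinase of interleukin 1 and Toll-like receptor signalling, 2.49 ± 0.23), the chemokine Ccl6 (2.33 ± 0.19) and Padi4 (a histone citrullinating enzyme of neutrophils, 2.30 ± 0.22). The nuclear receptor Nr4a1 rose by 2.00 ± 0.19, and Cebpe and Cebpa, transcription factors of granulocyte development, by 1.68 ± 0.10 and 1.32 ± 0.11. The largest falls at 6 h were those of Rpp25, a subunit of RNase P (-1.99 ± 0.24), Vcan, the proteoglycan versican (-1.96 ± 0.33), B3gnt5, an enzyme of glycolipid synthesis (-1.82 ± 0.15), Bex6 (-1.74 ± 0.20) and the potassium channel Kcnj2 (-1.60 ± 0.24). At 12 h the cytokine Il1f9 (3.24 ± 0.29), Ccrl2, a receptor for chemerin (3.11 ± 0.24), and Pram1, an adaptor protein of granulocytes (2.77 ± 0.14), stood among the largest rises. At that time Bex6 (-2.86 ± 0.19), Tespa1 (-2.58 ± 0.21) and Nt5e, the ecto-nucleotidase CD73 (-1.75 ± 0.16), fell.

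At 6 h 2860 of 19938 genes were called, 1158 up and 1702 down, and 821 of them changed by at least 1.5-fold (468 up and 353 down). At 12 h 4306 genes were called, 1970 up and 2336 down, with 1215 past 1.5-fold (715 up and 500 down). Within batches, the 6 h effect called 1636 genes in batch 1 (688 up and 948 down) and 2181 in batch 2 (1103 up and 1078 down). Without untreated replicate 4, 1774 genes were called at 6 h.

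Of 17 retinoic acid targets, 10 rose and 0 fell at 6 h (11 and 0 adjusted over the list alone), with a mean change of 1.00 (camera adjusted p = 5.85e-13, and adjusted p = 0.0244 with an estimated correlation). Besides Cyp26a1, they included Dhrs3, a retinal reductase (2.29 ± 0.19), Bhlhe40 (2.30 ± 0.21) and Rarg (1.62 ± 0.14). At 12 h 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a mean of 0.92 (adjusted p = 3.76e-09, and adjusted p = 0.0692 with an estimated correlation). Of 24 secondary granule and mature neutrophil genes, 7 rose and 1 fell at 6 h (7 and 2 adjusted over the list alone), with a mean of 0.42 (adjusted p = 0.000579, and adjusted p = 0.481 with an estimated correlation). At 12 h 13 rose and 2 fell (17 and 2 adjusted over the list alone), with a mean of 0.72 (adjusted p = 8.16e-12, and adjusted p = 0.0848 with an estimated correlation). Of 20 stem and progenitor genes, 0 rose and 8 fell at 12 h (0 and 9 adjusted over the list alone), among them Adgrg1 (-1.56 ± 0.12), Cd34 (-1.38 ± 0.14) and Gata2 (-1.32 ± 0.16). Their mean was -0.32 (adjusted p = 0.00576, and adjusted p = 0.0970 with an estimated correlation).

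In transgenic PML/RARA leukaemia, of 22 Myc and ribosome biogenesis genes, 1 rose and 14 fell at 6 h (1 and 17 adjusted over the list alone), with a mean of -0.39 (adjusted p = 1.94e-10, and adjusted p = 0.164 with an estimated correlation). At 12 h 0 rose and 18 fell by either adjustment, including the list alone, with a mean of -0.41 (adjusted p = 1.33e-09, and adjusted p = 0.129 with an estimated correlation). Of 32 cell cycle genes, 1 rose and 8 fell at 6 h (1 and 9 adjusted over the list alone), with a mean of -0.17 (adjusted p = 0.000455, and adjusted p = 0.541 with an estimated correlation). At 12 h 0 rose and 23 fell (0 and 24 adjusted over the list alone), with a mean of -0.40 (adjusted p = 8.16e-12, and adjusted p = 0.152 with an estimated correlation).

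Of 10 coagulation genes in this leukaemia, 4 rose and 0 fell at 6 h (6 and 0 adjusted over the list alone), with a mean of 0.47 (adjusted p = 0.00545, and adjusted p = 0.140 with an estimated correlation). At 12 h 6 rose and 1 fell by either adjustment, including the list alone, with a mean of 0.59 (adjusted p = 0.00100, and adjusted p = 0.0692 with an estimated correlation). Of 20 interferon response genes, 4 rose at 6 h (5 adjusted over the list alone) and 12 at 12 h (13 adjusted over the list alone) and 0 fell, with means of 0.27 (adjusted p = 0.0345) and 0.53 (adjusted p = 5.78e-06). Both calls were lost with an estimated correlation (adjusted p = 0.541 and 0.149). Irf1 rose by 1.67 ± 0.15 at 6 h and the viral RNA sensor Oasl2 by 1.52 ± 0.28 at 12 h. Of 17 apoptosis regulators, 6 rose and 2 fell at both times (8 and 2 at 6 h, 8 and 3 at 12 h adjusted over the list alone), with means of 0.17 (adjusted p = 0.0168, and adjusted p = 0.294 with an estimated correlation) and 0.15 (adjusted p = 0.0481, and adjusted p = 0.296 with an estimated correlation). The death effector Bak1 rose by 0.60 ± 0.08 at 6 h, and the survival gene Bcl2 fell by 0.76 ± 0.09 at 12 h. Of 17 immediate early and stress genes, 5 rose and 0 fell at 6 h by either adjustment, including the list alone, with a mean of 0.35 (adjusted p = 0.000455, and adjusted p = 0.200 with an estimated correlation). At 12 h 6 rose and 1 fell by either adjustment, with a mean of 0.23, a median of -0.01 (adjusted p = 0.0274, and adjusted p = 0.372 with an estimated correlation). The interferon call at 6 h was lost without untreated replicates 2 (0.25) or 4 (0.24) and without RA replicates 3 (0.28), 4 (0.27) or 7 (0.27). At 12 h the apoptosis call was lost without untreated replicates 1 (0.15) or 4 (0.14) or RA replicates 5 (0.15) or 8 (0.14). The immediate early call was lost without untreated replicate 2 (0.18).

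Lists of markers of other marrow cells were tested as well. Of 9 erythroid markers, 2 rose at 6 h (7 adjusted over the list alone) and 7 at 12 h (8 adjusted over the list alone), and 0 fell, with means of 0.90 (adjusted p = 0.00241) and 0.87 (adjusted p = 0.00313). Neither held with an estimated correlation (adjusted p = 0.485 and 0.426). B cell markers had a mean of 0.46 at 6 h with 0 of 10 called by either adjustment, including the list alone (adjusted p = 0.0115, and adjusted p = 0.541 with an estimated correlation). Without 6 h untreated replicate 4 neither 6 h call held, with means of 0.39 for erythroid and 0.12 for B cell markers. Of 11 monocyte and macrophage markers, 4 rose at 12 h (8 up and 1 down adjusted over the list alone), with a mean of 0.31 (adjusted p = 0.00422, and adjusted p = 0.149 with an estimated correlation). Megakaryocyte and platelet markers had a mean of 0.34 at 12 h (adjusted p = 0.183) and were called in no contrast.

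The RA effect at 12 h was compared with that at 6 h in the same leukaemia. This contrast lay outside the naming rule, so its genes were chosen after their values were seen. Il1f9 rose by 2.46 ± 0.41 more at 12 h than at 6 h (adjusted p = 0.00514), Slco4c1, an organic anion transporter, by 1.87 ± 0.30 (adjusted p = 0.0046), and Itgam by 0.71 ± 0.16 (adjusted p = 0.0408). Tespa1 (-1.76 ± 0.31, adjusted p = 0.00564), Id1, an inhibitor of helix-loop-helix factors (-1.22 ± 0.25, adjusted p = 0.0220), and Zbtb16, the mouse PLZF gene (-0.95 ± 0.21, adjusted p = 0.0351), had a lower RA effect at 12 h than at 6 h. In all, 46 genes were called, 32 up and 14 down (69.6% up), against 31 up and 28 down (52.5% up) after another quantile normalization. Leaving out single arrays gave between 16 and 95 calls. The count was 22 without 6 h untreated replicate 1, 24 without replicate 3 and 22 without replicate 4. It was 28 without 6 h RA replicate 1, 19 without replicate 2 and 83 without replicate 4. It was 95 without 12 h untreated replicate 1, 16 without replicate 3 and 18 without replicate 4.

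By list, the RA effect at 12 h exceeded that at 6 h for secondary granule and mature neutrophil genes by a mean of 0.30 (1 up over all genes and 8 up adjusted over the list alone, adjusted p = 3.71e-09, and adjusted p = 0.207 with an estimated correlation). Monocyte and macrophage markers moved by 0.31 (0 called over all genes and 4 up adjusted over the list alone, adjusted p = 8.47e-05) and primary granule genes by 0.19 (0 and 5 up adjusted over the list alone, adjusted p = 0.0129). With an estimated correlation these gave adjusted p = 0.172 and 0.325. Interferon genes moved by 0.25 (adjusted p = 0.000532), stroma and endothelium markers by 0.36 (adjusted p = 0.00323), T and NK cell markers by 0.20 (adjusted p = 0.0129) and PML nuclear body genes by 0.08 (adjusted p = 0.0271). With an estimated correlation these 4 gave adjusted p = 0.325, 0.325, 0.207 and 0.394. Cell cycle genes moved by -0.23 (adjusted p = 3.71e-09, and adjusted p = 0.325 with an estimated correlation) and stem and progenitor genes by -0.15 (adjusted p = 0.0265, and adjusted p = 0.222 with an estimated correlation). Single arrays ended 4 of these calls. The stem and progenitor call was lost without 6 h untreated replicate 1 (-0.12) or 6 h RA replicate 1 (-0.14). Without 6 h untreated replicate 3 the calls of primary granule genes (0.16), T and NK cell markers (0.12) and PML nuclear body genes (0.07) were lost. The last was also lost without 6 h RA replicate 8 (0.07), 12 h RA replicates 1 (0.07) or 3 (0.07), or 12 h untreated replicates 3 (0.03) or 4 (0.06). It was 0.11 without 12 h untreated replicate 2.

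**Figure D1:**
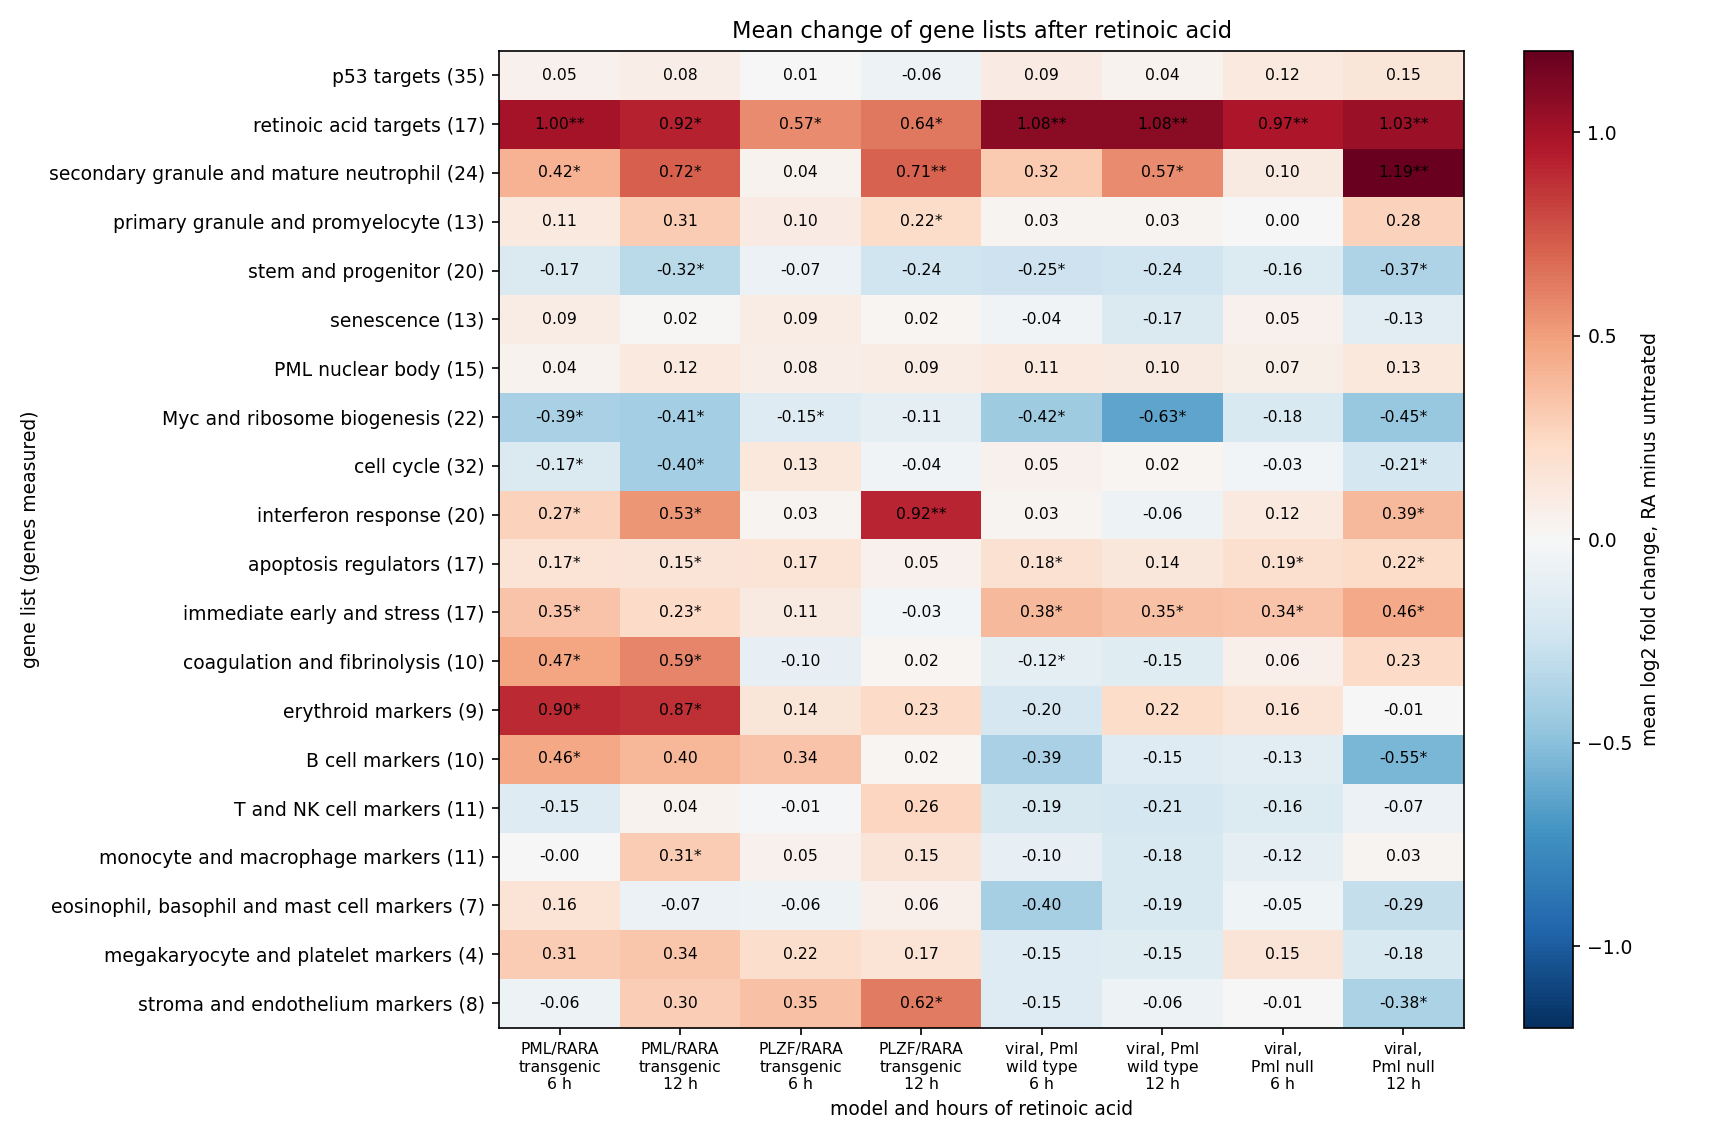
Mean log2 change of each gene list (RA minus untreated) in the 8 RA effects, with the number of genes measured in parentheses. One asterisk marks a camera adjusted p below 0.05 with the preset correlation, and a second asterisk the same with an estimated correlation, which retinoic acid targets reached in 5 of the 8 effects.

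The next comparison asked how the PLZF/RARA leukaemia responds to RA (4 RA and 2 untreated arrays at each time). Cyp26a1 rose by 3.36 ± 0.74 at 6 h and by 3.97 ± 0.74 at 12 h. Tubb6, a beta tubulin, rose by 1.97 ± 0.26 at 6 h and Fcgr3, an IgG receptor, by 1.47 ± 0.18. Cebpa rose by 1.09 ± 0.15. The survival kinase Pim2 fell (-1.58 ± 0.13 at 6 h and -1.53 ± 0.13 at 12 h), as did Bex6 (-1.88 ± 0.27 and -1.99 ± 0.27). At 12 h interferon-induced genes stood among the largest rises, such as the antiviral genes Oas2 (2.40 ± 0.45), Oasl2 (2.30 ± 0.40), Ddx60 (2.11 ± 0.31) and Rtp4 (2.41 ± 0.48).

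At 6 h 439 genes were called, 290 up and 149 down (66.1% up), against 239 up and 246 down (49.3% up) after another quantile normalization. At least 1.5-fold changes were 247 (156 up and 91 down). At 12 h 803 genes were called, 490 up and 313 down, with 483 past 1.5-fold (327 up and 156 down). With 2 untreated arrays, single arrays mattered at 6 h. Without untreated replicate 1 there were 56 calls, without untreated replicate 2 there were 104, without RA replicate 1 there were 236 and without RA replicate 2 there were 915. The 6 h call of Cyp26a1 was then lost without untreated replicate 1 (3.23, adjusted p = 0.205) and without untreated replicate 2 (3.49, adjusted p = 0.109). At 12 h there were 438 calls without untreated replicate 1 and 451 without untreated replicate 2.

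Of 17 retinoic acid targets, 4 rose and 1 fell in PLZF/RARA leukaemia at 6 h (7 and 1 adjusted over the list alone), with a mean of 0.57 (adjusted p = 0.000515, and adjusted p = 0.434 with an estimated correlation). At 12 h 4 rose and 0 fell (8 and 1 adjusted over the list alone), with a mean of 0.64 (adjusted p = 1.46e-07, and adjusted p = 0.0869 with an estimated correlation). Secondary granule and mature neutrophil genes had 11 up and 0 down of 24 at 12 h (17 and 0 adjusted over the list alone), with a mean of 0.71 (adjusted p = 1.74e-22, and adjusted p = 0.00911 with an estimated correlation). Interferon response genes had 11 up and 0 down of 20 (16 and 0 adjusted over the list alone), with a mean of 0.92 (adjusted p = 2.86e-23, and adjusted p = 0.00382 with an estimated correlation). Of 13 primary granule genes, 3 rose and 0 fell at 12 h (4 and 1 adjusted over the list alone), with a mean of 0.22 (adjusted p = 0.0210, and adjusted p = 0.412 with an estimated correlation). Myc and ribosome biogenesis genes had a mean of -0.15 at 6 h with 0 up and 1 down of 22 by either adjustment, including the list alone (adjusted p = 0.000243, and adjusted p = 0.663 with an estimated correlation). Stroma and endothelium markers had 3 of 8 up at 12 h (6 adjusted over the list alone) and a mean of 0.62 (adjusted p = 1.71e-06, and adjusted p = 0.108 with an estimated correlation). Without 12 h untreated replicate 1 the 12 h means were 0.45 for neutrophil genes, 0.38 for stroma and endothelium markers and 0.17 for primary granule genes. The last call was then lost (adjusted p = 0.159). Without 6 h RA replicate 4 the mean of Myc and ribosome biogenesis genes was -0.09.

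The difference in RA effect between the 2 transgenic fusions was tested directly, averaged over both times. RA raised F3 by 2.90 ± 0.51 more with PML/RARA than with PLZF/RARA (adjusted p = 0.00033), Suox by 2.87 ± 0.40, Ccl6 by 2.25 ± 0.22, Fcgr4 by 2.13 ± 0.25 and Nr4a1 by 1.89 ± 0.23. In group means, F3 went from 5.30 ± 0.16 to 8.09 ± 0.93 (SD) with PML/RARA at 6 h (n = 4 and 8), and from 5.45 ± 0.04 to 5.72 ± 0.08 with PLZF/RARA (n = 2 and 4). Pml had a higher RA effect with PML/RARA, by 0.84 ± 0.14 (adjusted p = 0.00011), as did Bhlhe40 (1.72 ± 0.25), Padi4 (1.60 ± 0.26), Ncf1 (1.47 ± 0.21), Cebpe (0.89 ± 0.12) and Rara (0.65 ± 0.11). Kit had a difference of -1.04 ± 0.20, Jag1, a Notch ligand, -1.40 ± 0.16, the adhesion gene Pecam1 -1.15 ± 0.12, the actin regulator Fmnl2 -1.37 ± 0.17 and Stra8 -1.53 ± 0.23. Cyp26a1 had a difference of -0.01 and did not pass.

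In total 1480 genes differed in RA effect, 668 up and 812 down, with 556 past 1.5-fold (301 up and 255 down). At single times, 302 genes were called at 6 h (180 up and 122 down) and 585 at 12 h (355 up and 230 down), and with the arrays of batch 1 only 1012 genes (476 up and 536 down). The count was 875 without PLZF/RARA 6 h untreated replicate 1, 889 without 6 h untreated replicate 2 and 766 without 12 h untreated replicate 2.

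Coagulation and fibrinolysis genes had a higher RA effect with PML/RARA, with 5 of 10 up and 0 down (6 and 0 adjusted over the list alone) and a mean difference of 0.57 (adjusted p = 9.2e-05, and adjusted p = 0.0206 with an estimated correlation, but 0.326 at 12 h alone). Besides F3 these were the urokinase receptor Plaur (1.04 ± 0.13), the urokinase gene Plau (0.80 ± 0.18) and thrombomodulin, Thbd (0.61 ± 0.13). Retinoic acid targets had 5 up and 0 down of 17 (7 and 2 adjusted over the list alone), with a mean of 0.36 (adjusted p = 0.000507, and adjusted p = 0.363 with an estimated correlation). Immediate early and stress genes had 3 up and 0 down of 17 (5 and 0 adjusted over the list alone), with a mean of 0.25 (adjusted p = 0.00522, and adjusted p = 0.363 with an estimated correlation). Neutrophil genes had 6 up and 1 down of 24 (7 and 2 adjusted over the list alone), with a mean of 0.19 (adjusted p = 0.0192, and adjusted p = 0.659 with an estimated correlation). Their difference was 0.38 at 6 h (adjusted p = 5.15e-06, and adjusted p = 0.355 with an estimated correlation) and 0.01 at 12 h (adjusted p = 0.974). The call over both times was lost without PLZF/RARA 12 h untreated replicate 2 (0.06), 12 h RA replicate 4 (0.18), 6 h untreated replicate 2 (0.12) or 6 h RA replicate 1 (0.19). The mean was 0.32 without 12 h untreated replicate 1. Cell cycle genes had 0 up and 12 down of 32 (0 and 20 adjusted over the list alone), with a mean of -0.33 (adjusted p = 1.11e-11, and adjusted p = 0.363 with an estimated correlation). Myc and ribosome biogenesis genes had 0 up and 6 down of 22 (1 and 14 adjusted over the list alone), with a mean of -0.27 (adjusted p = 7.47e-06, and adjusted p = 0.363 with an estimated correlation). Erythroid markers had a mean of 0.70 with 0 of 9 called by either adjustment, including the list alone (adjusted p = 0.00858), and stroma and endothelium markers -0.37 with 1 of 8 down by either adjustment (adjusted p = 0.0140). With an estimated correlation both had adjusted p = 0.602. The erythroid call was lost without PML/RARA 6 h untreated replicate 4 (0.44). The stroma call was lost without PML/RARA 12 h untreated replicate 1 (-0.29) or PLZF/RARA 12 h untreated replicate 1 (-0.25) or 6 h RA replicate 2 (-0.32). At 12 h alone neither retinoic acid targets (0.28, adjusted p = 0.117), immediate early genes (0.26, adjusted p = 0.0859) nor erythroid markers (0.64, adjusted p = 0.136) were called. The interferon list did not differ on average over the times. Its mean was 0.24 at 6 h alone (adjusted p = 0.0836) and -0.39 at 12 h alone (adjusted p = 4.56e-05, and adjusted p = 0.344 with an estimated correlation). Senescence genes had a mean difference of -0.00 (adjusted p = 0.957) and were called in no contrast.

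**Figure D2:**
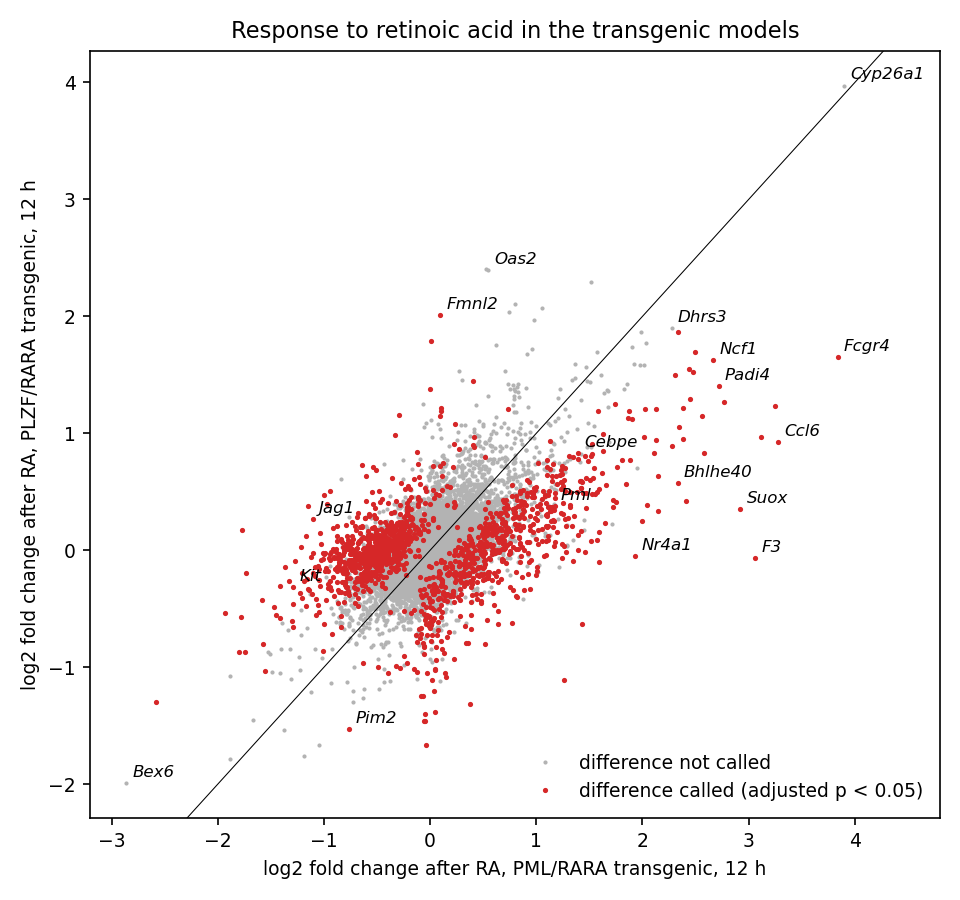
Log2 fold change after RA at 12 h in PML/RARA (horizontal) and PLZF/RARA (vertical) transgenic leukaemia for each of 19938 genes, with the 1480 genes whose RA effect differed over both times in red and the line of equal change. F3 rose in PML/RARA leukaemia (3.06) and lies near 0 on the vertical axis, and Cyp26a1 lies near the line.

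Untreated leukaemias of the 2 fusions were compared to show how far they differed before RA (4 PML/RARA and 2 PLZF/RARA arrays at each time). Untreated PML/RARA leukaemia had higher Ms4a6b (4.81 ± 0.18), F13a1, a coagulation factor subunit (4.14 ± 0.24), Rtp4 (4.04 ± 0.35) and Oas2 (3.64 ± 0.33). It had lower Car4, a carbonic anhydrase (-7.55 ± 0.09), Thy1, a surface protein of lymphoid and progenitor cells (-5.14 ± 0.10), the matricellular gene Ccn3 (-5.06 ± 0.14) and the interferon-induced membrane gene Ifitm1 (-4.15 ± 0.18). Rara was lower by 1.24 ± 0.09. Between them 5049 genes differed, 2611 up and 2438 down, with 1795 past 1.5-fold (876 up and 919 down). This contrast is one between leukaemias, and the number of leukaemias behind each fusion is not given in the labels.

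Of 20 interferon genes, 18 were higher in untreated PML/RARA leukaemia and 0 lower by either adjustment, including the list alone, with a mean of 1.17 (adjusted p = 3.95e-13, and adjusted p = 0.0656 with an estimated correlation). All 9 erythroid markers were higher, with a mean of 2.63 (adjusted p = 4.61e-08, and adjusted p = 0.252 with an estimated correlation). Of 11 T and NK cell markers, 7 were higher and 1 lower (9 and 1 adjusted over the list alone), with a mean of 0.36 (adjusted p = 0.00262, and adjusted p = 0.0982 with an estimated correlation). B cell markers (5 of 10 up, 6 adjusted over the list alone) had a mean of 0.56 (adjusted p = 0.0372) and stroma and endothelium markers (5 of 8 up by either adjustment) of 0.48 (adjusted p = 0.0372), both with adjusted p = 0.558 with an estimated correlation. Eosinophil, basophil and mast cell markers had 4 of 7 down (6 adjusted over the list alone) and a mean of -0.90 (adjusted p = 0.00313, and adjusted p = 0.264 with an estimated correlation). Cell cycle genes were higher by a mean of 0.25 (15 up and 1 down of 32, and 17 and 1 adjusted over the list alone, adjusted p = 0.000556), neutrophil genes by 0.28 (10 up and 3 down over all genes, adjusted p = 0.0225), and Myc and ribosome biogenesis genes lower by a mean of -0.23 (0 up and 7 down over all genes, adjusted p = 0.00313). Each of these 3 had adjusted p = 0.558 with an estimated correlation. Without PLZF/RARA untreated replicate 1 of 12 h or 6 h in turn, the calls were lost for neutrophil genes (0.15 and 0.20), B cell markers (0.39 and 0.55) and stroma and endothelium markers (0.36 and 0.42). The latter 2 were also lost without PML/RARA 12 h untreated replicate 1 (0.54 and 0.40). Leaving out PML/RARA 6 h untreated replicate 3 ended the B cell call (0.45), and replicate 4 the stroma call (0.42). The p53 list was lower by a mean of -0.27 (1 up and 9 down of 35, and 1 and 10 adjusted over the list alone, adjusted p = 0.00417, and adjusted p = 0.359 with an estimated correlation), with Perp at -2.46 ± 0.29 and Sesn2 at -1.27 ± 0.13.

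In the viral model, the signal of Pml was looked at first, since the model contrasts arrays labelled Pml wild type with arrays labelled Pml null. Pml was not lower in the arrays labelled Pml null. Before RA, its mean at 6 h was 9.27 ± 0.19 (SD, n = 4) in the arrays labelled Pml null and 9.32 ± 0.09 (SD, n = 4) in the Pml wild type arrays. The untreated difference, wild type minus null, was 0.04 ± 0.13 (SE, adjusted p = 0.916). Over all viral arrays Pml ran from 9.08 to 10.2 in the arrays labelled Pml null and from 9.20 to 10.2 in the wild type, and 2 of the 18 arrays labelled Pml null lay below the lowest wild type array. With RA at 6 h Pml rose in both backgrounds, by 0.70 ± 0.13 in the arrays labelled Pml null (adjusted p = 0.000407) and by 0.53 ± 0.13 in wild type (adjusted p = 0.00737). Within batch 3 alone the 6 h changes were 0.68 and 0.45 and were not called. At 12 h the changes were 0.49 (adjusted p = 0.132) and 0.53 (adjusted p = 0.0961). These values come from the 1 probe set of Pml, transcript cluster 10594053, so they do not show what the signal in arrays labelled Pml null is made of, and the comparisons of the viral model are comparisons of labels.

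**Figure D3:**
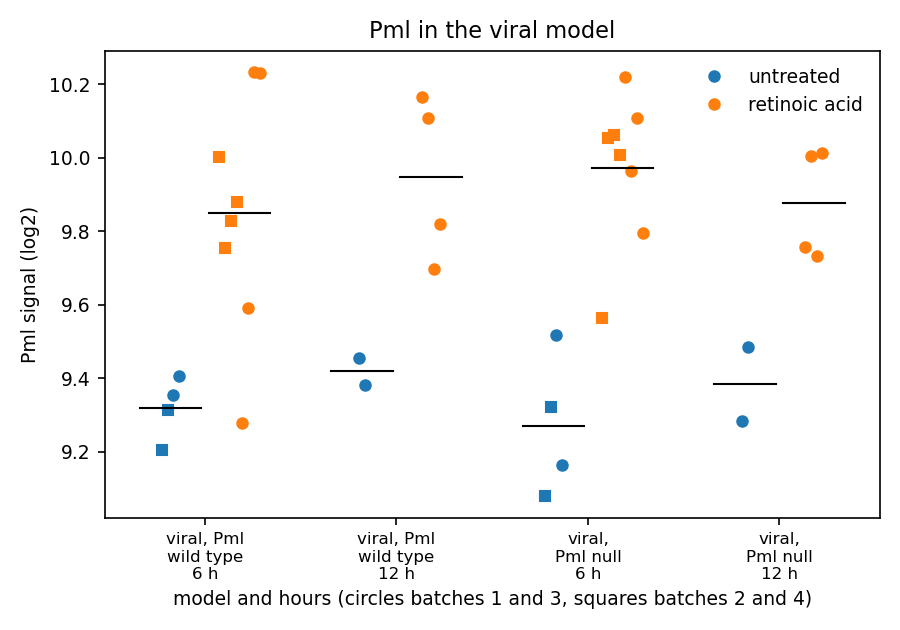
Pml signal (log2) on each of the 36 viral arrays by background label, time and treatment, with black lines at the group means. Arrays labelled Pml null (9.08 to 10.2) cover nearly the range of wild type arrays (9.20 to 10.2).

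RA effects in the viral model were estimated with 8 RA and 4 untreated arrays at 6 h and 4 and 2 at 12 h in each background. In Pml wild type leukaemia Cyp26a1 rose by 4.50 ± 0.31 at 6 h and 4.96 ± 0.44 at 12 h, Ccrl2 by 4.11 ± 0.21 and 4.05 ± 0.30, and Suox by 4.02 ± 0.31 and 3.66 ± 0.44. Vdr, the vitamin D receptor, rose by 3.06 ± 0.33 and 2.84 ± 0.47, Hic1 by 2.96 ± 0.24 and 3.08 ± 0.33, Vat1 by 2.75 ± 0.21 and 2.78 ± 0.29, and Nr4a1 by 2.64 ± 0.19 and 2.28 ± 0.28. Among the genes that fell at both times were Bex6 (-2.48 ± 0.35 and -3.04 ± 0.49), St8sia4, an enzyme of polysialic acid synthesis (-1.81 ± 0.25 and -1.93 ± 0.36), and the lectin Clec4n (-1.94 ± 0.21 and -1.96 ± 0.30). Kit (-1.55 ± 0.30) and arginase 2, Arg2 (-1.75 ± 0.27), fell at 6 h.

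In leukaemia labelled Pml null Cyp26a1 rose by 5.10 ± 0.31 at 6 h and 5.76 ± 0.44 at 12 h, Suox by 4.69 ± 0.31 and 3.91 ± 0.44, Ccrl2 by 4.03 ± 0.21 and 3.97 ± 0.30, Irak2 by 3.54 ± 0.22 and 3.09 ± 0.32, and Ncf1 by 2.90 ± 0.37 and 3.94 ± 0.53. Chil1, a chitinase-like protein, rose by 4.09 ± 0.55 at 12 h, Pram1 by 4.04 ± 0.59, Fcgr3 by 3.06 ± 0.36 and Ngp, a neutrophil granule protein, by 1.99 ± 0.23. Bex6 (-2.99 ± 0.35 and -2.91 ± 0.49) and P2ry14, a receptor for UDP-glucose (-1.87 ± 0.23 and -1.61 ± 0.32), fell at both times.

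In Pml wild type leukaemia 1969 genes were called at 6 h (1084 up and 885 down, with 709 past 1.5-fold, 422 up and 287 down) and 1217 at 12 h (605 up and 612 down, with 735 past 1.5-fold, 376 up and 359 down). Within batches the 6 h effect called 291 genes in batch 3 (234 up and 57 down) and 1314 in batch 4 (645 up and 669 down). Without 6 h untreated replicate 1 the count was 1300, and without 12 h untreated replicates 1 and 2 in turn it was 287 and 297. In leukaemia labelled Pml null 2263 genes were called at 6 h (990 up and 1273 down, with 785 past 1.5-fold, 427 up and 358 down) and 1207 at 12 h (842 up and 365 down, with 752 past 1.5-fold, 569 up and 183 down). The 12 h calls were 69.8% up, against 796 up and 562 down (58.6% up) after another quantile normalization. Within batches the 6 h effect called 366 genes in batch 3 (251 up and 115 down) and 1006 in batch 4 (537 up and 469 down). The count was 1361 and 1355 without 6 h untreated replicates 1 and 2 in turn, and 632 and 376 without 12 h untreated replicates 1 and 2 in turn.

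Retinoic acid targets were called up in both backgrounds. In wild type, 11 of 17 rose and 0 fell at 6 h by either adjustment, including the list alone, and 8 and 0 at 12 h (10 and 0 adjusted over the list alone). The means were 1.08 (adjusted p = 9.05e-14) and 1.08 (adjusted p = 3.18e-12), with adjusted p = 0.00561 and 0.0107 with an estimated correlation. In the arrays labelled Pml null, 7 rose and 0 fell at 6 h (8 and 1 adjusted over the list alone) and 7 and 0 at 12 h (12 and 0 adjusted over the list alone). The means were 0.97 (adjusted p = 6.83e-09) and 1.03 (adjusted p = 1.17e-11), with adjusted p = 0.0491 and 0.0157 with an estimated correlation.

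Secondary granule and mature neutrophil genes had a mean of 0.57 in wild type at 12 h, with 5 up and 0 down of 24 (5 and 1 adjusted over the list alone, adjusted p = 0.00971, and adjusted p = 0.509 with an estimated correlation). The 4 RA arrays split into pairs, with list scores of 12.29 and 12.28 in replicates 1 and 2, and 11.23 and 11.31 in replicates 3 and 4, against 11.17 and 11.25 untreated (exact p = 0.200). The call was lost without RA replicates 1 (0.39) or 2 (0.40). In arrays labelled Pml null at 12 h, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a mean of 1.19 (adjusted p = 2.07e-14, and adjusted p = 0.0283 with an estimated correlation). Stem and progenitor genes had a mean of -0.25 in wild type at 6 h (0 up and 3 down of 20, 0 and 4 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.138 with an estimated correlation) and of -0.37 in arrays labelled Pml null at 12 h (0 up and 5 down over all genes, adjusted p = 0.00287, and adjusted p = 0.0686 with an estimated correlation). Interferon genes in arrays labelled Pml null at 12 h had 4 up and 0 down of 20 (5 and 0 adjusted over the list alone), with a mean of 0.39 (adjusted p = 0.000229, and adjusted p = 0.330 with an estimated correlation).

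Myc and ribosome biogenesis genes had a mean of -0.42 in wild type at 6 h (1 up and 6 down of 22, 1 and 9 adjusted over the list alone, adjusted p = 6.67e-06), of -0.63 at 12 h (0 and 4, 0 and 12 adjusted over the list alone, adjusted p = 8.12e-08) and of -0.45 in arrays labelled Pml null at 12 h (1 up and 1 down over all genes, adjusted p = 7.49e-05). With an estimated correlation these gave adjusted p = 0.452, 0.419 and 0.483. Cell cycle genes in arrays labelled Pml null at 12 h had 0 up and 3 down of 32 (0 and 5 adjusted over the list alone), with a mean of -0.21 (adjusted p = 5.52e-07, and adjusted p = 0.327 with an estimated correlation).

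Apoptosis regulators had means of 0.18 in wild type at 6 h (4 up and 0 down of 17, 5 and 0 adjusted over the list alone, adjusted p = 0.0298), 0.19 in arrays labelled Pml null at 6 h (6 and 0, 8 and 0 adjusted over the list alone, adjusted p = 0.0270) and 0.22 at 12 h (5 and 0, 5 and 1 adjusted over the list alone, adjusted p = 0.0166). With an estimated correlation these gave adjusted p = 0.138, 0.0891 and 0.0836. Immediate early and stress genes had 3 up and 0 down of 17 in each viral effect, with means of 0.38 and 0.35 in wild type at 6 h and 12 h (adjusted p = 0.0298 and 0.0364, and adjusted p = 0.654 and 0.606 with an estimated correlation). In arrays labelled Pml null the means were 0.34 and 0.46 (adjusted p = 0.0459 and 0.00323, and adjusted p = 0.953 and 0.464 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell in wild type and 4 and 0 in arrays labelled Pml null at 6 h. Coagulation genes in wild type at 6 h had 1 up and 3 down of 10 by either adjustment, including the list alone, with a mean of -0.12 (adjusted p = 0.0298, and adjusted p = 0.165 with an estimated correlation). Serpinb2, an inhibitor of plasminogen activators, fell by 1.30 ± 0.16, while F3 rose by 1.77 ± 0.36. In arrays labelled Pml null at 12 h, B cell markers had a mean of -0.55 with 0 of 10 called (adjusted p = 0.0434, and adjusted p = 0.53 with an estimated correlation). Without 12 h untreated replicate 2 that mean was 0.36, and without untreated replicate 1 it was -1.46. The call was also lost without RA replicates 1 (-0.49), 2 (-0.39) or 3 (-0.53). Stroma and endothelium markers had a mean of -0.38 with 2 of 8 down by either adjustment (adjusted p = 0.0408, and adjusted p = 0.488 with an estimated correlation). That call was lost without untreated replicate 2 (-0.19) or RA replicates 1 (-0.39) or 2 (-0.30).

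Other calls of these lists also depended on single arrays. In wild type at 6 h the apoptosis call was lost without RA replicates 6 (0.19) or 8 (0.17). The immediate early call was lost there without untreated replicate 4 (0.34) or RA replicates 3 (0.27), 5 (0.39) or 6 (0.38). So was the coagulation call without untreated replicate 3 (-0.09) or RA replicates 5 (-0.09), 6 (-0.08) or 7 (-0.14). At 12 h the immediate early call was lost there without untreated replicate 2 (0.30) or RA replicates 3 (0.33) or 4 (0.16). In arrays labelled Pml null the apoptosis call was lost at 6 h without RA replicate 2 (0.19) and at 12 h without untreated replicate 1 (0.20). The immediate early call at 6 h was lost there without untreated replicates 2 (0.28) or 4 (0.26) or RA replicates 2 (0.37), 4 (0.33) or 5 (0.30).

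The difference in RA effect between the backgrounds, wild type minus arrays labelled Pml null, was tested over both times. RA raised Vdr by 2.30 ± 0.41 more in wild type (adjusted p = 0.0018) and Nr4a1 by 2.15 ± 0.24 more (adjusted p = 2.3e-06). Bcl2l15 (1.88 ± 0.36), Wee2 (1.59 ± 0.19), Cd40lg (1.38 ± 0.27), the chemokine Ccl17 (1.33 ± 0.27) and Themis2 (1.08 ± 0.15) had higher RA effects in wild type as well. Arg2 had a lower RA effect in wild type (-2.90 ± 0.34, adjusted p = 3.9e-06), as did Chil1 (-2.64 ± 0.48), the matrix gene Tgfbi (-2.16 ± 0.37), Fcgr3 (-1.73 ± 0.31), Clec4n (-1.61 ± 0.26), Stra8 (-1.49 ± 0.25), the adaptor Scimp (-1.46 ± 0.27) and Ngp (-0.95 ± 0.20). Pml had a difference of -0.07 (adjusted p = 1.00).

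There were 226 calls for this difference, 76 up and 150 down, with 150 past 1.5-fold (43 up and 107 down). At single times there were 71 at 6 h (20 up and 51 down) and 23 at 12 h (6 up and 17 down), and within batches 42 in batch 3 (12 up and 30 down) and 30 in batch 4 at 6 h (10 up and 20 down). Without wild type 12 h untreated replicates 1 and 2 in turn there were 126 and 122 calls, and 99 without 12 h untreated replicate 2 of the arrays labelled Pml null. By list, coagulation genes had a mean difference of -0.28 (0 up and 1 down of 10, adjusted p = 0.000393, and adjusted p = 0.0491 with an estimated correlation, but 0.231 and 0.194 at 6 h and 12 h alone), the 1 call being that of Serpinb2 (-1.09 ± 0.20). Neutrophil genes had a mean of -0.20 (1 up and 3 down of 24, 3 and 10 adjusted over the list alone, adjusted p = 0.000393, and adjusted p = 0.519 with an estimated correlation). Their difference was 0.21 at 6 h (adjusted p = 0.516) and -0.62 at 12 h (adjusted p = 1.41e-08, and adjusted p = 0.194 with an estimated correlation). Over both times it was -0.11 and -0.13 without wild type 12 h RA replicates 3 and 4 in turn, and -0.12 without 12 h untreated replicate 2 of the arrays labelled Pml null. Interferon genes had a mean of -0.27 (0 up and 2 down of 20 over all genes, adjusted p = 1.64e-05, and adjusted p = 0.482 with an estimated correlation). Myc and ribosome biogenesis genes had a mean of -0.21 (0 up and 1 down of 22 over all genes, adjusted p = 0.00347, and adjusted p = 0.785 with an estimated correlation). This call was lost without wild type 12 h RA replicate 2 (-0.15), and without 12 h untreated replicate 1 (-0.16) or RA replicate 1 (-0.15) of the arrays labelled Pml null. Cell cycle genes had a mean of 0.16 (0 called over all genes, 1 up adjusted over the list alone, adjusted p = 5.89e-07, and adjusted p = 0.482 with an estimated correlation). At 6 h and 12 h alone, the difference was -0.09 and -0.45 for interferon genes (adjusted p = 0.106 and 2.4e-06). It was 0.08 and 0.23 for cell cycle genes (0.106 and 1.41e-08) and -0.24 and -0.18 for Myc and ribosome biogenesis genes (0.00153 and 0.188). No call held with an estimated correlation (adjusted p = 0.255 for interferon and cell cycle at 12 h, 0.764 for Myc at 6 h).

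Untreated viral leukaemias of the 2 backgrounds differed widely before RA. Wild type arrays had higher Gal, the neuropeptide galanin (6.14 ± 0.14), Ms4a3, a membrane protein of myeloid precursors (5.77 ± 0.18), Car4 (5.73 ± 0.19), the macrophage lectin Mgl2 (5.65 ± 0.16) and Ceacam10 (5.55 ± 0.15). In group means, Ms4a3 at 6 h was 12.55 ± 0.07 in wild type and 6.89 ± 0.36 in arrays labelled Pml null (SD, n = 4 each). Il17rb, a receptor for interleukin 25 (-4.63 ± 0.20), Il6st, the shared receptor of the interleukin 6 family (-3.65 ± 0.25), the mast cell protease Cpa3 (-3.30 ± 0.37), Cd40lg (-3.14 ± 0.22) and Kit (-1.79 ± 0.30) were lower in wild type. The contrast called 4151 genes, 1977 up and 2174 down, with 1683 past 1.5-fold (977 up and 706 down), and within batches 3126 genes in batch 3 (1566 up and 1560 down) and 1978 in batch 4 at 6 h (1057 up and 921 down).

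Neutrophil genes were higher in untreated wild type arrays, with 21 up and 1 down of 24 over all genes and a mean of 1.68 (adjusted p = 2.94e-18, and adjusted p = 0.0102 with an estimated correlation). Interferon genes had 18 up and 0 down of 20 (19 and 0 adjusted over the list alone), with a mean of 1.17 (adjusted p = 2.85e-17, and adjusted p = 0.0102 with an estimated correlation). Coagulation genes had 7 up and 1 down of 10 (8 and 1 adjusted over the list alone), with a mean of 0.67 (adjusted p = 0.00013, and adjusted p = 0.0102 with an estimated correlation). The p53 list had 13 up and 5 down of 35 over all genes and a mean of 0.19 (adjusted p = 0.0348, and adjusted p = 0.188 with an estimated correlation), with Trp53inp1 at 1.74 ± 0.12 and Sesn1 at -1.93 ± 0.13. Apoptosis regulators had 7 up and 2 down of 17 over all genes (mean 0.17, adjusted p = 0.0339, and adjusted p = 0.0991 with an estimated correlation). Immediate early genes had 4 up and 0 down of 17 (5 and 0 adjusted over the list alone, mean 0.49, adjusted p = 0.00620, and adjusted p = 0.439 with an estimated correlation). Monocyte and macrophage markers were higher by a mean of 0.77, with 6 of 11 up (9 adjusted over the list alone, adjusted p = 1.75e-05, and adjusted p = 0.0764 with an estimated correlation). T and NK cell markers were higher by a mean of 0.52, with 5 up and 2 down of 11 over all genes (adjusted p = 0.0339, and adjusted p = 0.188 with an estimated correlation). Primary granule genes had 5 up and 5 down of 13, with a mean of 0.66 (adjusted p = 0.366). Without 12 h replicate 1 of the arrays labelled Pml null the calls of the p53 list (0.18), apoptosis regulators (0.16) and T and NK cell markers (0.48) were lost. The first 2 were also lost without wild type 12 h replicate 1 (0.17 and 0.16). The p53 list was also not called without wild type 6 h replicate 2 (0.18) or 6 h replicate 4 of the arrays labelled Pml null (0.18).

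For the RA effect at 12 h minus that at 6 h in viral Pml wild type leukaemia, 0 genes were called and 298 had an unadjusted p below 0.05. Neutrophil genes had a mean of 0.25 (adjusted p = 0.00521), Myc and ribosome biogenesis genes of -0.21 (adjusted p = 0.0184) and erythroid markers of 0.42 (adjusted p = 0.0184), with no member called and with adjusted p = 0.976 with an estimated correlation for each. Leaving out 1 array ended these calls in 4, 8 and 6 of 18 fits. The means ran from 0.08 to 0.43, from -0.33 to -0.10 and from 0.20 to 0.64. Across all contrasts 94 list shifts were called, of which 13 were also called with an estimated correlation. These were retinoic acid targets in 5 RA effects (transgenic PML/RARA at 6 h and all 4 viral effects), neutrophil genes in PLZF/RARA and in arrays labelled Pml null at 12 h and in untreated viral arrays, interferon genes in PLZF/RARA at 12 h and in untreated viral arrays, and coagulation genes in both differences in RA effect and in untreated viral arrays.

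The series is about p53 activation, so the p53 target list was followed across all RA effects. Its mean change was small everywhere and was called in none of the 8 RA effects. In transgenic PML/RARA leukaemia at 6 h 8 of 35 members rose and 6 fell by either adjustment, including the list alone, with a mean of 0.05 and a median of -0.00 (adjusted p = 0.980), and at 12 h 9 rose and 3 fell (9 and 6 adjusted over the list alone), with a mean of 0.08 and a median of -0.01 (adjusted p = 0.279). Mdm2, the ubiquitin ligase that limits p53, rose by 0.44 ± 0.08 and 0.38 ± 0.07, and in group means from 9.39 ± 0.19 (SD, n = 4) to 9.78 ± 0.10 (SD, n = 8) at 6 h. Ddit4, an inhibitor of mTOR signalling, rose by 1.81 ± 0.29 at 6 h, and Trp53inp1, a p53-induced regulator of cell death and autophagy, by 1.28 ± 0.16 at 12 h, while the DNA repair gene Xpc fell (-0.67 ± 0.14 and -0.66 ± 0.13). In PLZF/RARA leukaemia 1 rose and 2 fell at 6 h by either adjustment (mean 0.01, median -0.01, and camera pointing down, adjusted p = 0.124), and 3 rose and 2 fell at 12 h (3 and 6 adjusted over the list alone, mean -0.06, adjusted p = 0.748). The sign of these means depended on single arrays. The 6 h mean was -0.04 without untreated replicate 2 and -0.05 without RA replicate 1, and the 12 h mean was 0.04 without untreated replicate 1. Mdm2 had changes of -0.08 and 0.11 there and did not pass.

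In viral Pml wild type leukaemia 8 p53 list members rose and 3 fell at 6 h (9 and 4 adjusted over the list alone, mean 0.09, adjusted p = 0.875), and 2 rose and 5 fell at 12 h (6 and 8 adjusted over the list alone, mean 0.04, median -0.04, camera pointing down, adjusted p = 0.771). In arrays labelled Pml null 8 rose and 3 fell at 6 h (9 and 5 adjusted over the list alone, mean 0.12, median -0.06, adjusted p = 0.774), and 4 rose and 0 fell at 12 h (5 and 1 adjusted over the list alone, mean 0.15, adjusted p = 0.285). Mdm2 rose by 0.37 ± 0.08 in wild type and by 0.40 ± 0.08 in arrays labelled Pml null at 6 h. Pmaip1, which encodes the death activator Noxa, rose by 0.64 ± 0.11 and 0.80 ± 0.11, Ddit4 by 2.12 ± 0.44 and 2.95 ± 0.44, and Xpc fell (-0.53 ± 0.10 and -0.60 ± 0.10). The difference between the backgrounds in the RA effect on the list was -0.07, with 0 of 35 members called by either adjustment, including the list alone (adjusted p = 0.150).

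The difference between the fusions in the RA effect on the p53 list was 0.09, with a median of 0.05 (adjusted p = 0.0852), and 6 members had a higher RA effect with PML/RARA and 0 a lower one (7 and 1 adjusted over the list alone). They were Sesn2, a stress-induced regulator of metabolism (0.95 ± 0.16), Phlda3, an inhibitor of Akt (0.50 ± 0.11), Cd82 (0.45 ± 0.12) and Mdm2 (0.39 ± 0.09), with Btg2 (0.63 ± 0.18) and Sesn1 (0.43 ± 0.13), both chosen after their values were seen. For Phlda3 the difference came with falls in both fusions at 6 h, of -0.32 with PML/RARA and -0.75 ± 0.13 with PLZF/RARA, and the latter was not called without PLZF/RARA 6 h untreated replicate 1 (-0.53). Without that array 3 of the 35 members were called up in the difference, while the mean over the 6 was 0.52 ± 0.09 against 0.56 ± 0.08 with it. Cd82 was not called without it (0.42) nor without PLZF/RARA 12 h untreated replicate 1 (0.39). By the share of all genes called up, 1.17 of 35 members would be expected (Fisher's exact p = 0.000979, two-sided, with genes treated as independent). That test was chosen after the 6 members were seen, and the members are correlated (estimated correlation 0.0995), so its p is too small. Camera, the test set before, did not call the list (adjusted p = 0.0852, and adjusted p = 0.602 with an estimated correlation).

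On single arrays, the p53 list score was higher with RA by 0.09 in viral Pml wild type leukaemia at 6 h, where 7 of 8 RA arrays lay above the highest untreated array, and by 0.12 in arrays labelled Pml null, where 8 of 8 did. Each rise came mostly from Ddit4 and had an exact p = 0.00444, the smallest that 225 arrangements allow (adjusted p = 0.0373). In transgenic PML/RARA leukaemia the difference was 0.04 at 6 h (exact p = 0.274) and 0.08 at 12 h (exact p = 0.0202, adjusted p = 0.101). In PLZF/RARA leukaemia it was 0.01 (exact p = 0.933) and -0.06 (exact p = 0.533), and in the viral model at 12 h 0.04 in wild type (exact p = 0.667) and 0.15 in arrays labelled Pml null (exact p = 0.133), where 15 arrangements allow no p below 0.0667. With the median of the list in place of the mean, the differences in transgenic PML/RARA leukaemia were -0.04 and -0.08, in PLZF/RARA leukaemia at 6 h -0.06, and in arrays labelled Pml null at 12 h -0.09 (exact p = 0.554, 0.273, 0.600 and 0.133). In the viral model at 6 h the median score was higher by 0.19 in wild type (exact p = 0.0178) and by 0.10 in arrays labelled Pml null (exact p = 0.0889), where the call was lost. Retinoic acid targets scored above the highest untreated array in 8 of 8 transgenic PML/RARA arrays with RA at 6 h (difference 0.98, exact p = 0.00595).

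**Figure D4:**
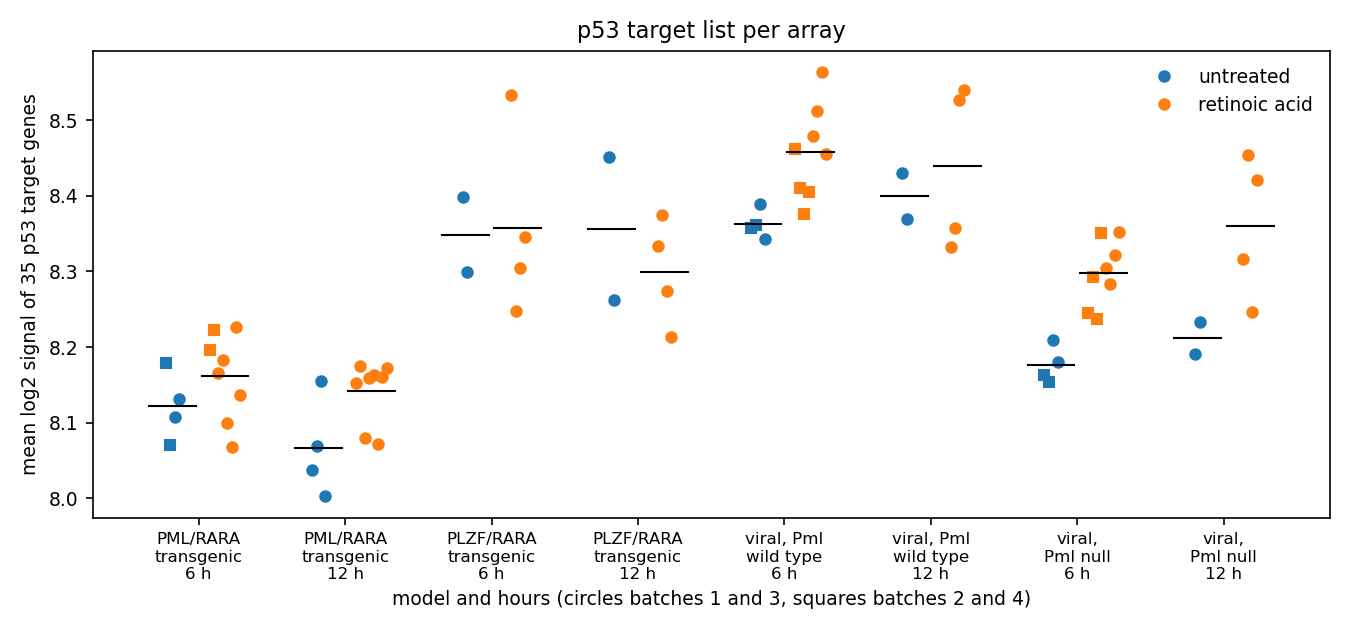
Mean log2 signal of the 35 measured p53 target genes on each of the 72 arrays by model, time and treatment, with black lines at the group means. All 8 RA arrays labelled Pml null at 6 h lie above the untreated arrays of their group, and in PLZF/RARA leukaemia the RA and untreated arrays overlap.

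The PML nuclear body list, which includes Pml, was called in none of the 8 RA effects. In transgenic PML/RARA leukaemia its mean change was 0.04 at 6 h, with 1 of 15 up and 0 down by either adjustment, including the list alone (adjusted p = 0.980), and 0.12 at 12 h, with 4 up and 1 down by either adjustment (adjusted p = 0.0925).

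The genes called in both models were counted to compare the transgenic and viral PML/RARA leukaemias. At 6 h 568 genes rose and 513 fell in both transgenic PML/RARA and viral Pml wild type leukaemia, where independent calls would give 63.0 and 75.5, and 4 moved in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.653. At 12 h 437 rose and 378 fell in both (59.8 and 71.7 if independent), 4 moved in opposite directions and r was 0.607. Without viral 12 h untreated replicates 1 and 2 in turn, 219 and 230 were shared in place of 815. Between the viral backgrounds at 6 h 581 rose and 476 fell in both (53.8 and 56.5 if independent), 3 moved in opposite directions and r was 0.764. Between the transgenic fusions at 6 h 170 rose and 48 fell in both (16.8 and 12.7 if independent), 2 moved in opposite directions and r was 0.408. These 218 became 40 and 59 without PLZF/RARA untreated replicates 1 and 2 in turn, 137 without RA replicate 1 and 344 without RA replicate 2.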

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

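Of the tests below, those on Pml, on the untreated viral difference, and on the 6 p53 list members were chosen only after the result was seen, while the splits of arrays and the count of members without single arrays were set before.

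Array medians stood apart in their groups by Dixon's test for PLZF/RARA 12 h RA replicate 1 (6.56), transgenic PML/RARA 12 h untreated replicate 3 (6.61) and 12 h RA replicate 4 (6.74). Chance would flag 3 of 60 tests, but all 3 flags fell in the 12 tests of array medians.

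Differences between groups that were called (lists with the preset correlation) were set apart as well. In genes called, they were the 1480 between the transgenic fusions, the 46 between 12 h and 6 h in transgenic PML/RARA leukaemia, and the 226 between the viral backgrounds.

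In list means, the RA effect of PML/RARA minus PLZF/RARA differed by 0.36 for retinoic acid targets, 0.19 for neutrophil genes, 0.25 for immediate early genes, 0.57 for coagulation genes and 0.70 for erythroid markers. It differed by -0.27 for Myc and ribosome biogenesis genes, -0.33 for cell cycle genes and -0.37 for stroma and endothelium markers. Only the coagulation shift kept its call with an estimated correlation (adjusted p = 0.363 to 0.659 for the others), though not at 12 h alone (adjusted p = 0.326).

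From 6 h to 12 h in transgenic PML/RARA leukaemia, the effect moved by 0.30 for neutrophil genes, 0.19 for primary granule genes, 0.0759 for PML nuclear body genes, 0.25 for interferon genes, 0.20 for T and NK cell markers, 0.31 for monocyte and macrophage markers and 0.36 for stroma and endothelium markers. It moved by -0.15 for stem and progenitor genes and -0.23 for cell cycle genes. With an estimated correlation none of these 9 was called (adjusted p = 0.172 to 0.394).

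Between Pml wild type and arrays labelled Pml null, the effect differed by -0.20 for neutrophil genes, -0.21 for Myc and ribosome biogenesis genes, 0.16 for cell cycle genes, -0.27 for interferon genes and -0.28 for coagulation genes. Again only coagulation kept its call with an estimated correlation (adjusted p = 0.482 to 0.785 for the others). At 6 h and 12 h alone it did not (adjusted p = 0.231 and 0.194).

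Of the 13767 probe sets without a single gene symbol, which were not assigned to genes, RA changed 326 and 709 in transgenic PML/RARA leukaemia at 6 h and 12 h, and 16 and 87 in PLZF/RARA leukaemia. In the viral model it changed 446 and 220 in Pml wild type and 349 and 134 in arrays labelled Pml null.

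Whether a grouping at random would call as many genes was tested by fitting up to 100 splits of the same arrays, the real one included. Only the real split (1 of 100) called as many genes for the RA effect in transgenic PML/RARA leukaemia at 6 h (2860, against 1408 for the highest other) and at 12 h (4306 against 2627). The same held (1 of 100 each) for arrays labelled Pml null at 6 h (2263 against 836), untreated transgenic leukaemias (5049 against 2196), untreated viral leukaemias (4151 against 2294), and 12 h minus 6 h (46 against 2). In viral Pml wild type leukaemia at 6 h, 2 of 100 splits called as many genes, since another split called 3075 against 1969. That split set RA replicates 3, 4 and 7 and untreated replicate 1 apart from the rest, which points to structure among these samples.

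The Pml signal was not lower in the arrays labelled Pml null. Single arrays with the wrong label would correlate better with the mean of the other background, and 0 of 36 did. A wrong label of a whole leukaemia might not show, so it stays open. Human PML of the fusion could hybridise to the mouse probes, but untreated Pml was -0.28 in PML/RARA minus PLZF/RARA leukaemia, which does not measure what the signal of a null array is made of. The probe set may read a part of the transcript that the disruption leaves in place, and with 1 probe set of Pml this stays open.

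For 6 p53 list members the RA effect was higher with PML/RARA than with PLZF/RARA. After another quantile normalization, which cannot undo that of the authors, 7 members were called up, so the normalization stays open. A single array stays open, as 3 members were called up without PLZF/RARA 6 h untreated replicate 1, but the mean difference of the 6 was 0.52 ± 0.09 (SE) then and 0.56 ± 0.08 before. These genes were picked from this contrast. A Pml-dependent rise of these genes would put their mean difference between the viral backgrounds above 0, and it was -0.08 with a 95% interval of -0.25 to 0.0921, so this stays open and rests on the labels.

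Untreated viral leukaemias of the 2 backgrounds differed in 4151 genes. A processing batch is not a likely source, since 1978 genes were called within 1 batch. A lower share of leukaemic cells in the arrays labelled Pml null would raise markers of other cells there. Instead 2 of 7 lists (monocyte, T and NK) were higher in wild type by both camera and fry. Neither held with an estimated correlation, so this stays open. A lower share in wild type stays open, as 0 lists were lower by both (stroma by fry alone, adjusted p = 0.0459). Other leukaemias in each background, whatever their Pml status, may differ as much. The labels do not tie arrays to single leukaemias, so this stays open.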

How the results depend on the processing

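The number of arrays limits these results, with 2 untreated arrays in each PLZF/RARA group and each viral group at 12 h. Where leaving out 1 array leaves an arm with 1 sample, the lone sample is assumed to vary like the other groups. The deposited values are summaries, so signal over background could not be judged per gene, and changes of dim genes are the least certain. No paired analysis was possible because the labels do not tie untreated and RA arrays to the same animal. The cause of the movements below was not tested.

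With a change of at least 1.5-fold required as well, 821 and 1215 genes were called in transgenic PML/RARA leukaemia at 6 h and 12 h, 247 and 483 in PLZF/RARA, 709 and 735 in viral Pml wild type and 785 and 752 in arrays labelled Pml null. The differences in RA effect kept 556 (transgenic) and 150 (viral) genes, and the untreated contrasts 1795 and 1683.

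Array weights raised the counts to 5639 in transgenic PML/RARA leukaemia at 6 h and 728 for 12 h minus 6 h. In the viral model they gave 3683 and 2658 in wild type, 4482 and 2031 in arrays labelled Pml null, 619 for the difference and 6419 for the untreated contrast.

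Without the arrays of unusual median (PLZF/RARA 6 h RA replicate 1 and viral wild type 6 h RA replicates 3 and 7, with medians of 6.81, 6.76 and 6.75), a setting chosen after the data were seen, PLZF/RARA at 6 h had 236 calls. One fit of all 72 arrays gave 283 there and 16 for 12 h minus 6 h. Only the arrays of the groups compared gave 34 and 350 calls in PLZF/RARA at 6 h and 12 h, and 651 in viral Pml wild type at 12 h. Untreated arrays of both times as controls gave 704 and 1318 in PLZF/RARA, 2945 in viral wild type and 2670 in arrays labelled Pml null at 12 h.

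Within batches, 1636 genes were called in batch 1 for transgenic PML/RARA at 6 h, 291 in batch 3 for viral wild type at 6 h, and 366 and 1006 in batches 3 and 4 for arrays labelled Pml null at 6 h. The viral difference had 42 and 30 calls in batches 3 and 4, and the untreated viral contrast 1978 in batch 4. By time, the transgenic difference had 302 and 585 calls and the viral difference 71 and 23 at 6 h and 12 h.

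Leaving out each array in turn gave 1774 to 3120 calls in transgenic PML/RARA at 6 h and 3548 to 4395 at 12 h, 56 to 915 and 438 to 853 in PLZF/RARA, 766 to 1999 for the transgenic difference, 4065 to 4954 for the untreated transgenic contrast and 16 to 95 for 12 h minus 6 h. In the viral model it gave 1300 to 2266 and 287 to 1304 in wild type, 1355 to 2631 and 376 to 1394 in arrays labelled Pml null, 99 to 260 for the difference, 3226 to 4053 for the untreated contrast and 0 to 1 for 12 h minus 6 h.

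Of the 94 called list shifts, 75 were called without the dimmest genes, 82 after another quantile normalization, 87 in one fit of all arrays and 13 with an estimated correlation. When each array was left out in turn, 61 kept their call in every fit and 33 lost it in at least 1. The mean of B cell markers in arrays labelled Pml null at 12 h ran from -1.46 to 0.36 over these fits.

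The mean change of the p53 list in PLZF/RARA at 6 h was -0.0383 after another quantile normalization and -0.0495 without arrays of unusual median, and ran from -0.0495 to 0.0578 over the fits leaving out 1 array. At 12 h it ran from -0.152 to 0.0371. The transgenic difference was 0.117 after another quantile normalization (adjusted p = 0.0463) and ran from 0.0398 to 0.134, and the viral difference from -0.0858 to -0.0492. With the median over the list, the p53 score moved by -0.0395 and -0.0819 in transgenic PML/RARA at 6 h and 12 h, -0.0642 in PLZF/RARA at 6 h and -0.0869 in arrays labelled Pml null at 12 h.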

Other observations

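A core of 61 genes rose and 7 fell in all 8 RA effects, and apart from those named under the rule these genes were chosen after their values were seen. Cyp26a1 rose by 3.36 to 5.76, Fcgr4 by 1.08 to 3.84, Dhrs3 by 1.36 to 2.29, Cebpa by 0.75 to 1.37 and Itgb2 by 0.67 to 2.03. The core also held Ltb4r1, a leukotriene B4 receptor of neutrophils (0.96 to 2.45), the NF-kappaB subunit Rel (0.66 to 1.48) and Gpx4, which reduces lipid peroxides (0.82 to 1.39). The p53 target Gadd45a (0.54 to 0.90) was among them. Bex6 (-3.04 to -1.74), Il15 (-2.25 to -0.93), Pim2 (-1.58 to -0.60) and St8sia4 (-2.50 to -0.87) fell in all 8. The 68 became 26 and 27 without PLZF/RARA 6 h untreated replicates 1 and 2 in turn, and 38 and 35 without viral Pml wild type 12 h untreated replicates 1 and 2 in turn.

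At 6 h alone, 122 genes rose and 29 fell in all 4 leukaemia types, where independent calls would give 0.0455 and 0.0360. These 151 became 34 and 46 without PLZF/RARA untreated replicates 1 and 2 in turn, and 99 without RA replicate 1. Calls are not independent between types that share a model, so these counts describe the overlap and are not a test of it. A further 296 genes rose at 6 h in the 3 PML/RARA types and were not called in PLZF/RARA leukaemia, which had fewer arrays, so this does not show a difference for each of them.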
